A study of Mus musculus with 6 samples.

How the data were processed

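The study profiled the brains of 5xFAD mice, which carry human transgenes with familial Alzheimer disease mutations and form amyloid plaques, and of wild-type C57BL/6J mice, all 8 months old. Per the labels, both cells and nuclei were fixed and barcoded with Split-seq, a method in which RNA is tagged inside the cell during several rounds of pooling and splitting over the wells of a plate. The first round used 48 wells, 16 for each of 3 preparations: microglia isolated from the pooled right cortex and hippocampus, nuclei of the left cortex, and nuclei of the left hippocampus. The specimen list names 24 specimens from 8 animals, 4 per genotype and 2 per genotype and sex, each loaded into 2 wells. After the first round all wells were mixed, and the 6 samples of the series are sublibraries of that 1 mix, so they are not biological replicates.

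The matrix deposited by the authors holds whole numbers for 64664 cells and 47707 genes, and these were treated as a score rather than as counts. The unit was read from the values, since no header or label names it. Of 113636952 stored entries, 33.5% were 0, which a table of raw counts would not store. The sum of scores per cell lay between 725 and 2503 although detected genes per cell ranged from 501 to 6851, and the commonest stored value was 3 in cells with 500 to under 600 detected genes but 0 in cells with 3000 to under 3300. Values that are scaled for depth, put on a log-like scale and rounded behave in this way, but the authors' formula is not given in the sources used here. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and the genome build was mm10. The aligner, the counting tool and the filter on cells are not given in the sources used here.

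The planned tests assumed raw counts and a link from each cell to an animal. The deposited score is not a count, and no map from the cells of the matrix to wells or animals was used here, so the matrix was handled as 1 pooled sample. No comparison of 5xFAD with wild-type mice or of females with males was made, and no p-value or count of changed genes was computed from cells. In place of counts scaled to CPM, a stored entry (also one of 0) was taken as detection of that gene in that cell, because a detection share has a true zero. The scores themselves were used for choosing variable genes, for clustering, for matching random gene lists and for picking some of the named genes, not for levels or folds.

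All deposited cells entered the work, since the lowest number of detected genes was 501 and mitochondrial genes made up at most 0.831% of a cell's score. Doublets were scored by simulating 32332 pairs of cells and counting simulated neighbours, as Scrublet does, written in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. The automatic threshold of scikit-image 0.26.0 on the simulated scores, 0.620, marked only 0.127% of cells and was therefore set aside. The 3218 cells with the highest scores, 4.98% of all, were left out instead, and 75.6% of simulated pairs scored above that threshold. This left 61446 cells.

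Cells were clustered on the 2000 most variable genes (in 20 bins of mean score, among genes detected in at least 50 cells), leaving out mitochondrial genes and every gene of the lists below unless it was also a cell type marker. Scores were scaled per gene and limited to 10 SD, 40 principal components were kept, and a shared-neighbour graph of the 15 nearest cells was split with the Leiden algorithm of python-igraph 0.11.9 at resolution 1, with 5 iterations and a fixed seed. A cluster was named after a cell type when at least 50% and at least 3 of the type's markers were detected in at least 5% of its cells and at least 2 times as often as elsewhere. It stayed unnamed when another lineage had 75% or more of its markers raised, or when its 10 leading genes held more markers of another type. A further cluster led by Eomes and Cdhr1 was left unnamed. Microglia-like cells were clustered again on their own with 20 components and with all list genes left out, markers included. Tables were handled with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

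Gene lists, cell type markers, the rule for named genes and the alternatives on variable genes, resolution and doublets were fixed before the data were examined. The 22 lists covered plaque-associated microglia genes (the DAM program), homeostatic microglia genes, interferon-stimulated genes, MHC and antigen presentation, complement and phagocytosis, early response genes linked to tissue dissociation, cell cycle, Alzheimer disease risk and processing genes, reactive astrocyte genes, disease-associated oligodendrocyte genes, neuronal activity-regulated genes, synaptic transmission, cholesterol synthesis and export, lysosome and autophagy, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrial transcripts, nuclear-retained long RNAs, sex-linked genes, senescence and stress, and extracellular matrix genes. Of 387 list entries 1 (Rigi) and of the markers of 27 types 3 (Ighm, Trac and Trbc2) had no column in the matrix under that symbol. Gene positions came from GENCODE M21 on mm10 (GRCm38), in which 47560 of the 47707 symbols had 1 entry.

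For each class of at least 200 cells the level of a list was the number of its members detected per cell, with an exact Poisson interval, among cells of 750 to under 1500 detected genes, a band that held cells of every class. The fold compared the class with all other kept cells of the band, with an exact conditional binomial interval. Both intervals treat each detection as an independent event. They can be too narrow where members are detected together in the same cells, and too wide where a gene is found in most cells. The size of this was not measured. Shares of cells carry Clopper-Pearson intervals. Unless stated otherwise, intervals are at the 95% level and cover counting error only, not differences between animals. A list also received the median log2 fold of its members detected in at least 100 cells, after adding 0.1 percentage points to each share, and the percentile of that median among 10000 random lists of equal size matched on mean score in 50 bins. Among microglia-like subclusters of at least 50 cells, all depths were used, 0.5 percentage points were added, and members had to be detected in at least 20 of these cells. Where a share was 0, the limit was set at 3 cells over the group, and folds against 0 were computed against that limit. Named genes were, per list, the 4 members with the highest mean score, over cells of all depths, in any class of at least 200 cells. The 4 with the largest fold of their highest class over all other cells were also named. Both were taken among members detected in at least 100 cells. For the microglia comparison the 4 members with the largest and the 4 with the smallest fold were added for the plaque-associated, homeostatic, interferon, MHC and dissociation lists. Some genes that this rule names are not reported here. In that rule mean scores stood in for CPM, detection shares for folds of CPM, and cells for UMIs (unique molecules).

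Several choices were made after values had been seen: detection in place of counts, the depth band, the doublet threshold, the thresholds for naming clusters, the joining of marker types into classes, the pairs of list and class taken as main results, a minimum of 1000 detected genes in place of 1000 UMIs, the pair of microglia-like subclusters compared, the subclustering of astrocyte-like and oligodendrocyte-like cells, and the neighbour graph. That graph replaced an earlier one that could not be rebuilt exactly, after list levels in the earlier clusters had been looked at. The steps were tested on simulated data. Of 8440 simulated cells with 14292 genes, 99.8% received their own class. These cells were drawn gene by gene from the detection rates of a few named classes, with no doublets or unnamed types. They were clustered on detection without leaving out list genes, so this share does not measure how well real cells were named. Among 100 genes whose rate was raised 2 times in 1 class, the median of found over true fold was 1.02. Of their intervals 98% held the true fold, and for 100 genes raised 4 times these were 1.00 and 96%. The true fold here was the ratio of expected detection shares at the simulated depths, not the 2 or 4 of the rate. These values therefore do not show how well a fold in rate is recovered. The 10 lists of changed genes all reached percentile 100, and 40 lists of unchanged genes had a median percentile of 43.5. Alternatives covered 4000 variable genes, Leiden resolutions of 0.5 and 2, doublets kept, a minimum of 1000 detected genes, cells of all depths, levels per detected gene, and a narrower depth band of 600 to under 900 genes for the microglia comparison. Where an alternative changed the clustering, microglia-like cells were subclustered again. The highest and lowest subclusters on the plaque-associated list were then chosen anew. The effect of the alternatives is given in the closing section.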

Results

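The data are a Split-seq survey of the brains of 8 mice at 8 months of age, 4 hemizygous 5xFAD animals and 4 wild-type animals with 2 females and 2 males in each genotype. Microglia isolated from the right hemisphere and nuclei of the left cortex and hippocampus were barcoded in 48 wells and mixed, and 6 sublibraries of the mix were sequenced. The series title gives the aim as cellular programs and sex-specific progression in a mouse model of Alzheimer disease. Cells could not be assigned here to a preparation, an animal, a genotype or a sex, so the pool is 1 sample with no replicates. The comparisons below are between cell classes and between groups of microglia within that pool, and none is between 5xFAD and wild-type mice or between females and males.

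The pool held 64664 cells and 47707 genes, of which 35966 were detected at least once. Cells had a median of 1532 detected genes, and 501 was the lowest number. UMI totals are unknown because the values are rounded normalized scores. Below, a share is the percentage of cells in which a gene was detected, and a list level is the number of its genes detected per cell. Unless stated otherwise both are for cells of 750 to under 1500 detected genes, and "other cells" are all remaining kept cells of that range. Within this range the median number of detected genes was 897 in microglia-like, 990 in astrocyte-like, 886 in oligodendrocyte-like, 1019 in oligodendrocyte precursor-like, 1010 in endothelial cell-like and 923 in vascular leptomeningeal cell-like cells. It was 1013 in choroid plexus cell-like, 985 in ependymal cell-like, 1241 in excitatory neuron-like, 1214 in dentate granule neuron-like, 1320 in CA neuron-like, 1220 in inhibitory neuron-like and 1291 in striatal projection neuron-like cells. The range held only 1688 of 13278 excitatory neuron-like and 560 of 5575 CA neuron-like cells, whose medians over all depths were 2473 and 2346. It held 1650 of 4793 oligodendrocyte-like cells, all deeper than that class's median of 678. Comparisons of these classes thus set shallow neurons against deep oligodendrocyte-like cells. Unless stated otherwise, values in parentheses are 95% intervals. They are Clopper-Pearson for shares and exact Poisson or conditional binomial for levels and folds. They cover counting error only, and those of levels and folds treat each detection as independent.

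The first comparison asked which cell classes the pool holds and in what shares. The named neuron classes made up 54.8% (54.4 to 55.2) of the 61446 cells kept after leaving out likely doublets, not counting unnamed clusters, of which several were led by neuronal genes. Excitatory neuron-like cells were the largest class at 21.6% (21.3 to 21.9, 13278 cells), followed by dentate granule neuron-like cells at 12.8% (12.6 to 13.1, 7877 cells) and hippocampal CA neuron-like cells at 9.07% (8.85 to 9.30, 5575 cells). Astrocyte-like cells were the largest glial class at 10.9% (10.6 to 11.1, 6682 cells), and oligodendrocyte-like cells, which form myelin, made up 7.80% (7.59 to 8.02, 4793 cells). Microglia-like cells, the resident macrophages of the brain, made up 2.96% (2.83 to 3.09, 1817 cells), although 16 of the 48 wells were loaded with isolated microglia.

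Inhibitory neuron-like cells made up 6.63% (4074 cells) and striatal projection neuron-like cells 4.64% (2850 cells). Oligodendrocyte precursor-like cells made up 2.79% (1713 cells). At the vessels, membranes and ventricles, endothelial cell-like cells made up 1.53% (940 cells), vascular leptomeningeal cell-like cells, the fibroblasts of the brain's coverings, 1.06% (654 cells), choroid plexus cell-like cells 0.977% (600 cells) and ependymal cell-like cells 0.780% (479 cells). Mural cell-like cells (0.221%, 136 cells) and perivascular macrophage-like cells (0.101%, 62 cells) were too few for the list comparisons. Among the 10 leading genes of a CA neuron-like cluster were Mndal, Ifi203 and Il16, known from immune cells, beside Homer3 and Slc9a4. A small inhibitory neuron-like cluster of 149 cells was led by Th, the rate-limiting enzyme of dopamine synthesis, with Pax6 and Sall3. Its median doublet score was 0.0672, against 0.0134 and 0.0101 in the larger inhibitory neuron-like clusters.

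A total of 11 clusters with 16.1% (15.9 to 16.4) of the cells stayed unnamed. The largest, 4609 cells or 7.5%, was led by Vipr2, Frmd7 and Lgr5. Others were led by Slc17a6 (a vesicular glutamate transporter) and Tshz2 (2112 cells), by the dopamine receptor gene Drd3 (819 cells), by the calcium-binding protein gene Calb2 (436 cells), by Ndnf (379 cells), and by Cdhr1 and Eomes (182 cells). An unnamed cluster of 272 cells, 0.443%, carried markers of both microglia and oligodendrocytes.

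**Figure D1:**
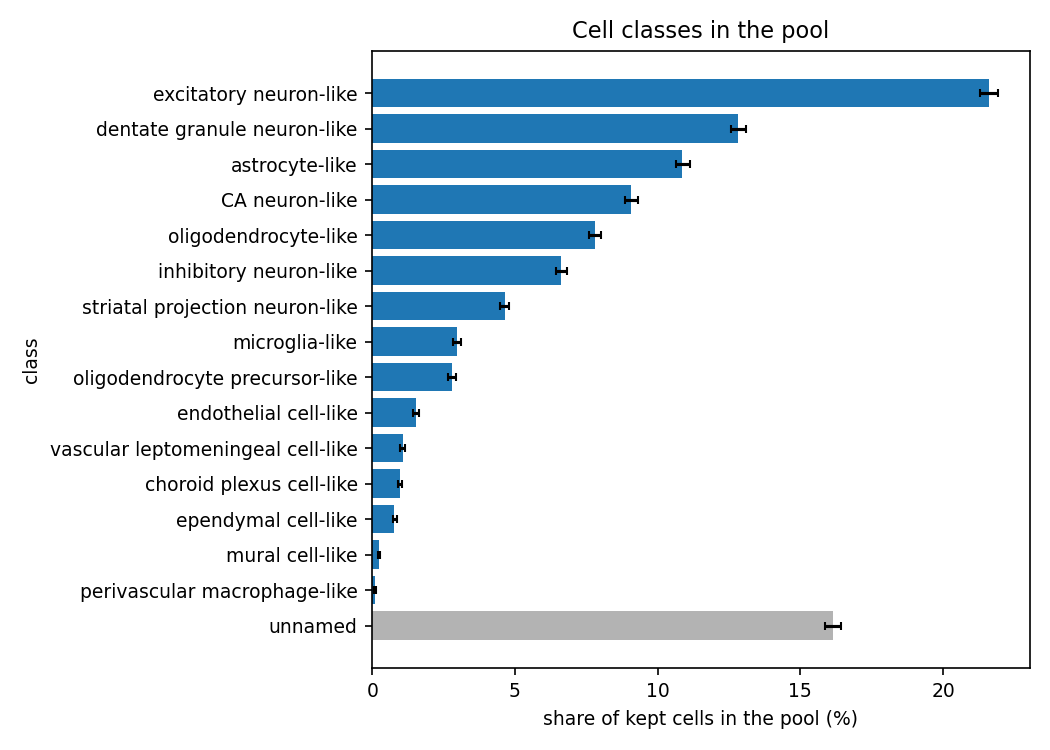
Bars give the share of the 61446 kept cells in each class (percent, x axis), and error bars are 95% Clopper-Pearson intervals. Excitatory neuron-like cells are the largest class at 21.6%, and the grey bar holds the 16.1% of cells in unnamed clusters.

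These are shares of a mix of 3 preparations and cannot be read as shares of the tissue, and the filter that cells passed to enter the matrix is not given in the sources used here. Among classes of at least 200 cells the median depth ran from 678 genes in oligodendrocyte-like to 2473 in excitatory neuron-like cells. With a minimum of 1000 detected genes the share was 0.557% for microglia-like, 1.08% for oligodendrocyte-like, 5.14% for astrocyte-like and 28.6% for unnamed clusters.

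The second comparison asked in which classes each gene list was detected most often. Microglia-like cells led in both microglia programs. They had 4.19 genes (4.05 to 4.34) of the plaque-associated (DAM) list per cell against 0.616 in other cells, a 6.81-fold difference (6.54 to 7.08), and 5.97 (5.79 to 6.15) of the homeostatic list against 0.810, a 7.37-fold difference (7.13 to 7.62). Of the members tested, 24 of 25 plaque-associated and 18 of 18 homeostatic genes were detected more often in this class than in other cells, and both medians (log2 2.77 and 4.96) lay at percentile 100 of matched random lists. These outcomes were close to fixed in advance, since both lists name microglia genes and the class was named by microglia markers. They check the naming of the class and give no further support. Astrocyte-like cells led in cholesterol genes, endothelial cell-like cells in interferon-stimulated genes, and neurons in activity and synaptic genes. All differences between classes are within 1 pool and have no replicate check.

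Among the plaque-associated genes, Itgax, an integrin of phagocytes on chromosome 7 (128129547 to 128150657, plus strand, mm10), was detected in 16.9% (14.3 to 19.8) of microglia-like cells and in 0 of 1688 excitatory neuron-like cells, which allows up to 0.178%. Its fold over other cells, at 0.0660%, was 256 (144 to 494). Trem2, a lipid-sensing receptor needed for the plaque response (chromosome 17, 48346401 to 48354147, plus strand), was detected in 17.2% (14.5 to 20.1), 161-fold (101 to 269) more often than in other cells, and in 0 of 1688 excitatory neuron-like cells. Cst7, an inhibitor of lysosomal proteases, reached 6.70% (147-fold, 71.4 to 339) with 0 of 3516 astrocyte-like cells, which allows up to 0.0853%, and Clec7a, a receptor for fungal sugars, 14.8% (104-fold, 68.0 to 163). Ctsd, a lysosomal protease, was found in 44.2% (40.6 to 47.9) against 1.83% of other cells. Some list members were more frequent outside microglia. Apoe, the main lipid carrier of the brain (chromosome 7, 19696109 to 19699188, minus strand), was detected in 38.2% (36.6 to 39.8) of astrocyte-like, 29.0% of microglia-like and 0.357% of CA neuron-like cells. Colec12, a scavenger receptor, was highest in vascular leptomeningeal cell-like cells (79.7%), and the motor protein gene Myo1e in endothelial cell-like cells (59.2%, 46.5% in microglia-like cells).

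The homeostatic genes Tgfbr1, a receptor of TGF-beta, and Mef2c, a transcription factor also used by neurons, were detected in 92.2% (90.1 to 94.0) and 83.2% of microglia-like cells, with 7.88% and 34.5% in other cells. Siglech, a lectin of microglia, was found in 55.1% (51.4 to 58.7), 132-fold (104 to 170) more often than in other cells. The folds were 111 for Selplg (35.5%), a ligand for selectins, 104 for the receptor gene Gpr34 (16.9%) and 152 for the fructose transporter gene Slc2a5 (10.1%). Without the 3 members that also served as markers the homeostatic fold was 6.12. In cells of all depths the homeostatic fold was 4.84, and per detected gene the plaque-associated fold was 10.4.

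Genes of Alzheimer disease risk and amyloid processing were also highest in microglia-like cells, at 6.73 (6.54 to 6.92) per cell against 3.36, a 2.00-fold difference (1.95 to 2.06), with 22 of 31 members higher (median log2 0.87, percentile 100) and ependymal cell-like cells lowest at 2.13. The lectin gene Cd33 was detected in 25.9% (22.8 to 29.2) of microglia-like and 0.178% of other cells, a 146-fold difference. Abi3, a regulator of the actin skeleton, reached 37.9% (136-fold) and Spi1, the transcription factor PU.1 of myeloid cells, 21.1% (98.7-fold), while Inpp5d, a lipid phosphatase that also served as a marker, reached 90.9%. Other members of the list were most frequent elsewhere. Bin1, a membrane-bending protein (chromosome 18, 32377230 to 32435737, plus strand), was detected in 70.6% (68.3 to 72.8) of oligodendrocyte-like, 52.0% of microglia-like and 2.87% of endothelial cell-like cells. Mapt, which encodes tau (chromosome 11, 104231390 to 104332090, plus strand), was detected in 92.4% (91.0 to 93.6) of oligodendrocyte-like, 65.5% of excitatory neuron-like and 2.55% of microglia-like cells. The depth range kept the shallow excitatory neuron-like and the deep oligodendrocyte-like cells, which limits this order. App, the amyloid precursor gene (chromosome 16, 84949685 to 85173766, minus strand), was found in 88.8% of oligodendrocyte-like, 88.5% of endothelial cell-like, 23.5% of microglia-like and 13.9% of astrocyte-like cells. The fold of this list was 1.16 in cells of all depths, and CA neuron-like cells had the highest level. Reads of the human transgenes were not separated from those of mouse App here.

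Complement and phagocytosis genes were highest in microglia-like cells at 2.08 (1.98 to 2.19) per cell against 0.388, a 5.36-fold difference (5.07 to 5.66) that was 3.38-fold without 4 markers, with 9 of 11 members higher (median log2 5.37, percentile 100). C3ar1, the receptor of complement fragment C3a, was detected in 7.37% of these cells, 161-fold more often than in others, and the integrin gene Itgam in 45.8%. Astrocyte-like cells came next at 1.19 per cell, 3.99-fold over other cells, from only 3 of 11 members. These included Mertk, a receptor for engulfing dying cells, with 78.6% in astrocyte-like and 87.4% in microglia-like cells, and C4b, complement component 4 (chromosome 17, 34728380 to 34743882, minus strand), with 30.7% (29.1 to 32.2) in astrocyte-like, 30.3% in oligodendrocyte-like and 1.07% in microglia-like cells. Gas6, the ligand of Mertk, was most frequent in choroid plexus cell-like cells (30.2%). Per detected gene the microglia fold of this list was 9.56.

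Lysosome and autophagy genes stood at 4.68 (4.53 to 4.84) per microglia-like cell against 0.862, a 5.44-fold difference (5.24 to 5.64), 4.22-fold without 2 markers, with 19 of 21 members higher (median log2 2.35, percentile 100). The cathepsin gene Ctss was detected in 52.1% of microglia-like cells, Ctsb in 31.4%, Laptm5, a lysosomal membrane protein of blood cells, in 30.8% (96.4-fold) and Ctsz in 14.3% (18.0-fold). Senescence and stress genes were sparse and highest in the same class, at 0.367 per cell (0.325 to 0.414) against 0.118, a 3.11-fold difference (2.74 to 3.53) with 5 of 9 members higher (median log2 0.67, percentile 98.7). Within that list Nfe2l2, the regulator of the antioxidant response, was detected in 23.5% of microglia-like cells, while Cdkn1a, an inhibitor of the cell cycle, was most frequent in endothelial cell-like cells (9.55%, 19.8-fold). Over all depths the folds were 2.74 for the lysosome and 1.81 for the senescence list, and the latter was then highest in endothelial cell-like cells.

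Interferon-stimulated genes were highest in endothelial cell-like cells at 2.12 (1.96 to 2.29) per cell against 0.361, a 5.87-fold difference (5.41 to 6.35), and next in microglia-like cells at 1.77 (1.68 to 1.87), 5.29-fold (4.98 to 5.61). In each of these classes 18 of 19 members were higher than in other cells, and the endothelial median (log2 2.62) lay at percentile 100. Striatal projection neuron-like cells were lowest at 0.102. Rnf213, a large ubiquitin ligase, was detected in 34.1% of endothelial cell-like and 0.442% of dentate granule neuron-like cells, and Ddx60, a helicase of the antiviral response, in 19.1% against 3.02% of other cells. The inhibitor of virus translation Ifit1 was found in 5.73% (3.43 to 8.91) of endothelial cell-like but 0.268% of microglia-like cells. The folds of Oas1a, which makes the signal that activates RNase L (7.33%), and Ifi44 (4.46%) over other cells were 25.4 and 40.8. Trim30a and Ifi204, a DNA sensor, were instead highest in microglia-like cells, at 25.7% and 11.8% (9.57 to 14.3), while Parp14 was similar at 15.6% in endothelial cell-like and 15.3% in microglia-like cells. Per detected gene the endothelial interferon fold was 9.04, and in cells of all depths the microglia fold was 3.47. Beside Flt1 (99.4%), endothelial cell-like cells carried the pericyte markers Rgs5 (64.3%), Abcc9 and Vtn (22.6% each), though Higd1b was rare (0.637%). The erythroid marker Hba-a1 was found in 9.87%. Whether this affects the list levels of the class was not tested. Mitochondrial transcripts (2.24 per cell, 8.75-fold) and ribosomal protein genes (0.790 per cell, 3.60-fold) were also highest in endothelial cell-like cells. That class led the reactive astrocyte and early response lists as well, and its MHC level overlapped that of microglia-like cells.

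Genes of MHC and antigen presentation followed the same classes, with 0.908 (0.805 to 1.02) per endothelial cell-like cell, 9.80-fold (8.62 to 11.1) over other cells, and 0.854 (0.789 to 0.923) per microglia-like cell, 11.1-fold (10.1 to 12.2). Of 10 members 9 were higher in the endothelial class (median log2 2.72, percentile 100) and 10 in the microglia class (median log2 3.15), and the level was 0.00784 in striatal projection neuron-like cells. B2m, the light chain of MHC class I (chromosome 2, 122147686 to 122153083, plus strand), was detected in 28.3% (23.4 to 33.7) of endothelial cell-like, 21.5% of microglia-like and 1.78% of cells outside the endothelial class. The class I heavy chain gene H2-D1 reached 17.5% in endothelial cell-like and 8.85% in microglia-like cells, H2-K1 11.5% and H2-Q7 5.10% in endothelial cell-like cells. Cd74, the invariant chain of class II (chromosome 18, 60803848 to 60812652, plus strand), was found in 6.43% (4.78 to 8.44) of microglia-like cells, 127-fold more often than in others, and Nlrc5, the activator of class I genes, in 19.2%. Cd74 was seen in only 0.0508% of other cells, so its fold rests on few cells. In cells of all depths the endothelial fold of this list was 15, and per detected gene it was 18.9, with 17.2 for microglia-like cells.

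**Figure D2:**
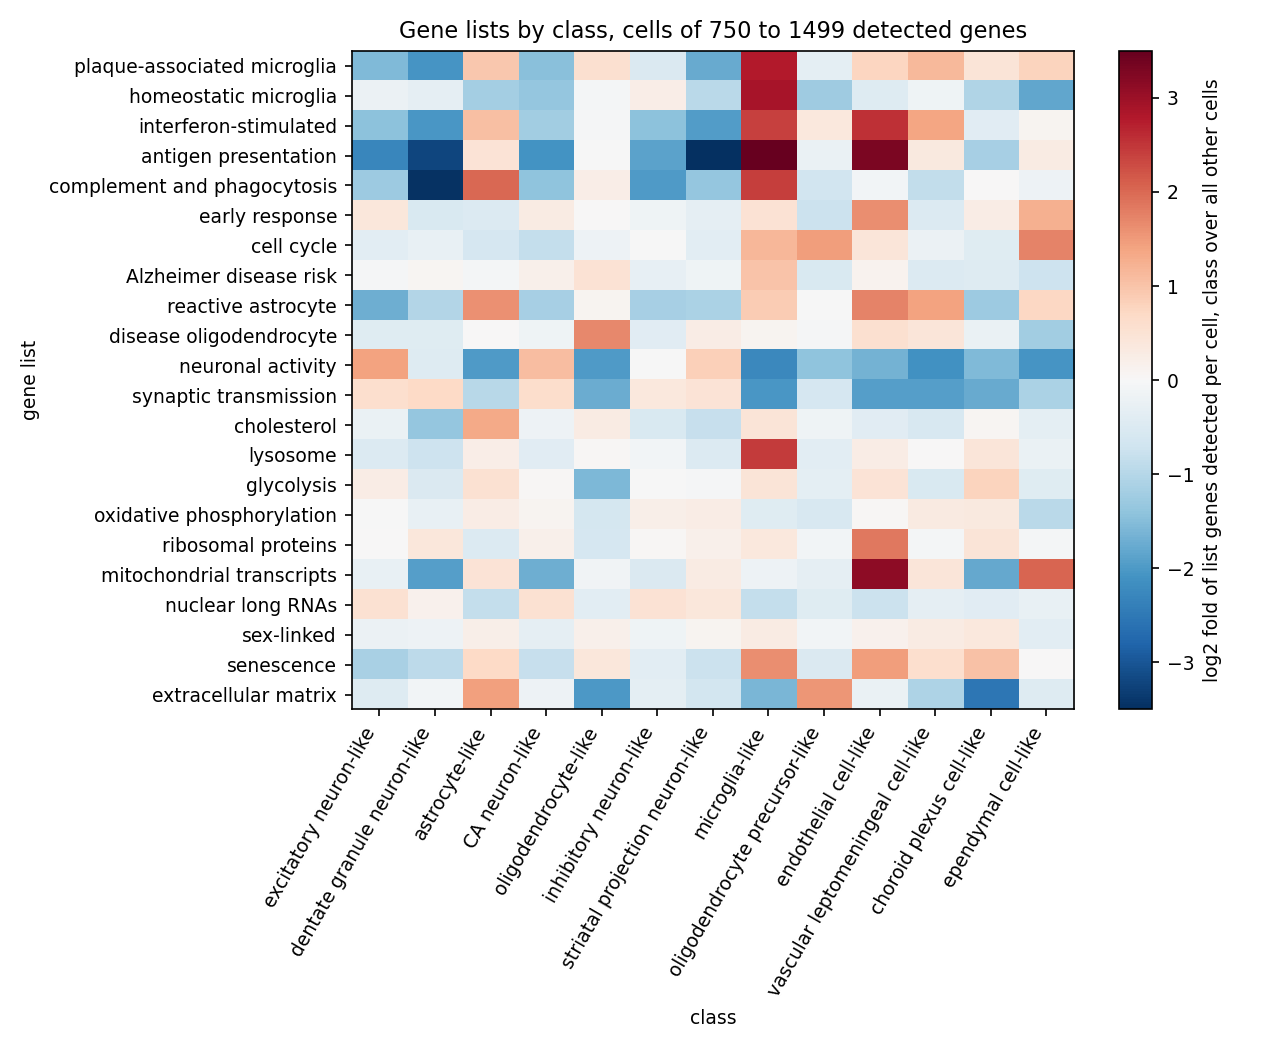
Colours give the log2 fold of list genes detected per cell in each class (x axis) over all other cells, for the 22 gene lists (y axis), in cells of 750 to under 1500 detected genes. Microglia-like cells are highest for the plaque-associated (6.81-fold) and homeostatic (7.37-fold) lists, and endothelial cell-like cells for the interferon-stimulated (5.87-fold) and mitochondrial (8.75-fold) lists.

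Reactive astrocyte genes were most frequent in endothelial cell-like cells, at 1.62 (1.49 to 1.77) per cell, 3.31-fold (3.02 to 3.62) over other cells with 11 of 18 members higher (median log2 0.68, percentile 99.5). Astrocyte-like cells had 1.14 (1.10 to 1.17), 3.02-fold (2.90 to 3.14), with 13 of 18 members higher (median log2 1.01, percentile 100). Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912, minus strand), was detected in 24.2% (22.7 to 25.6) of astrocyte-like and 0.325% of other cells, a 74.3-fold difference (56.5 to 99.5). The filament gene Vim (15%), Osmr, a receptor of oncostatin M (28.7%, 7.45% in astrocyte-like cells), and the proteoglycan gene Srgn (15.3%, 61.5-fold) were led by endothelial cell-like cells. Cp, the copper carrier ceruloplasmin, was led by vascular leptomeningeal cell-like cells (45.4%), and Cd109, which binds TGF-beta, by ependymal cell-like cells (17.0%, 38.6-fold).

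Disease-associated oligodendrocyte genes stood at 1.97 (1.90 to 2.04) per oligodendrocyte-like cell against 0.610, a 3.23-fold difference (3.10 to 3.35). Only 7 of 15 members were higher there, and the median (log2 -0.13) lay at percentile 90.9, so a few genes carried the level. Anln, a scaffold protein of the cytoskeleton found in myelin (chromosome 9, 22332012 to 22389188, minus strand), was detected in 47.8% (45.3 to 50.2) of oligodendrocyte-like cells, 43.6-fold more often than in others, and in 0 of 306 vascular leptomeningeal cell-like cells, which allows up to 0.980%. Il33, an alarmin cytokine kept in the nucleus (chromosome 19, 29925114 to 29960718, plus strand), was detected in 38.7% (36.3 to 41.1) of oligodendrocyte-like and 6.37% of astrocyte-like cells. Apod, a lipid carrier, was found in 45.7% of oligodendrocyte-like and 49.7% of vascular leptomeningeal cell-like cells, and Sgk1, a kinase induced by glucocorticoids, most often in striatal projection neuron-like cells (49.2%). In cells of all depths the fold of this list was 1.65.

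Cholesterol synthesis and export genes were highest in astrocyte-like cells at 2.28 (2.23 to 2.33) per cell against 0.918, a 2.49-fold difference (2.42 to 2.55), with 20 of 21 members higher (median log2 1.16, percentile 100), and lowest in dentate granule neuron-like cells at 0.501. Srebf2, the main activator of cholesterol synthesis, was detected in 23.8% and the sterol oxidase gene Msmo1 in 13.2% (5.28-fold) of astrocyte-like cells. The exporter gene Abca1 was most frequent in microglia-like cells (52.3%, 40.9% in astrocyte-like, 1.60% in excitatory neuron-like), Abcg1 in oligodendrocyte-like cells (23.6%), the sterol carrier gene Stard4 in endothelial cell-like cells (5.73%) and Npc2, which hands cholesterol out of the lysosome, in microglia-like cells (8.71%). The cholesterol fold was 1.25 in cells of all depths, and excitatory neuron-like cells had the highest level.

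Extracellular matrix genes, several of them parts of perineuronal nets, were highest in oligodendrocyte precursor-like cells at 3.60 (3.49 to 3.72) per cell, 2.90-fold (2.80 to 3.0) over other cells, with 8 of 12 members higher (median log2 0.93, percentile 100). Astrocyte-like cells followed at 2.84, and choroid plexus cell-like cells were lowest at 0.243. Tnr, which encodes tenascin-R, was detected in 99.9% and the proteoglycan gene Vcan in 85.3% (83.0 to 87.4, 27.1-fold) of the precursors, and Acan, the main proteoglycan of the nets, in 8.29% (19.4-fold). Sparcl1, a secreted protein of synapse formation (83.3%), Bcan (65.8%, 15-fold) and the link protein gene Hapln1 (8.11%) were led by astrocyte-like cells, and the link protein gene Hapln2, found at nodes of Ranvier, by oligodendrocyte-like cells (18.7%, 16.9 to 20.7, 168-fold). Cell cycle genes were rare, at 0.123 (0.0827 to 0.177) per ependymal cell-like cell, 3.35-fold (2.23 to 4.85) over other cells with 6 of 10 members higher (median log2 0.85, percentile 96.3), and at 0.0952 per oligodendrocyte precursor-like cell, 2.74-fold (2.20 to 3.38) with 9 of 10. Kif11, a motor of the mitotic spindle, led in the former (5.53%, 25.4-fold) and Mki67, a marker of dividing cells, in the latter (1.23%, 10.3-fold). Over all depths the fold of the cell cycle list was 1.66 in ependymal cell-like cells, and the precursors were highest.

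Neuronal activity-regulated genes were highest in excitatory neuron-like cells at 1.15 (1.10 to 1.20) per cell, 2.64-fold (2.51 to 2.77) over other cells, with 15 of 16 members higher (median log2 1.51, percentile 100). Dentate granule neuron-like cells had 0.380, 0.736-fold of other cells, and microglia-like cells 0.107. Nr4a1, a nuclear receptor induced by activity, was detected in 13.6% of excitatory neuron-like cells (3.37-fold), the hormone-processing protease gene Pcsk1 in 10.7%, and Arc, which regulates glutamate receptors at the synapse, in 5.51% (4.47 to 6.71) against 0 of 1061 oligodendrocyte precursor-like cells, which allows up to 0.283%. Bdnf, a neuronal growth factor (chromosome 2, 109674700 to 109727007, plus strand), went against the list's order. It was highest in dentate granule neuron-like cells at 11.1% (10.01 to 12.2), 7.04-fold (5.99 to 8.28) over other cells, with 0 of 314 endothelial cell-like cells, which allows up to 0.955%. Nr4a3 was highest in CA neuron-like cells (14.8%, 5.22-fold) and the synaptic scaffold gene Homer1 in striatal projection neuron-like cells (52.4%). Synaptic transmission genes were highest in CA neuron-like cells at 14.8 (14.5 to 15.1) per cell against 9.60, a 1.54-fold difference (1.51 to 1.58) with 23 of 23 members higher (median log2 0.69, percentile 99.9), then in excitatory neuron-like cells at 14.0. Microglia-like cells were lowest at 2.45. Stx1a, part of the vesicle fusion machinery, was detected in 20.3% of excitatory neuron-like cells, and the NMDA receptor gene Grin2a (99.8%) and the kinase gene Camk2b (77.6%) were highest in dentate granule neuron-like cells. Per detected gene the synaptic list turned to 0.971-fold (0.965 to 0.978) in CA neuron-like cells.

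Early response genes linked to tissue dissociation were highest in endothelial cell-like cells at 0.618 (0.534 to 0.711) per cell against 0.202, a 3.06-fold difference (2.64 to 3.54) with 12 of 14 members higher (median log2 1.22, percentile 99.96), and reached 0.290 in microglia-like cells, 1.41-fold (1.23 to 1.62), which turned to 0.630-fold (0.570 to 0.695) in cells of all depths. Nfkbia, an inhibitor of NF-kappa B, was detected in 20.1% (15.8 to 24.9) of endothelial cell-like cells (22.0-fold) and the transcription factor gene Jun in 8.60%. The chaperone gene Hsp90aa1 led in ependymal cell-like cells (39.6%, 5.02-fold) and Nfkbiz, another regulator of NF-kappa B, in microglia-like cells (11.1%). Glycolysis and hypoxia genes were highest in choroid plexus cell-like cells at 1.61 (1.49 to 1.74), 1.70-fold (1.58 to 1.84) over other cells with 14 of 16 members higher (median log2 0.64, percentile 99.8), and lowest in oligodendrocyte-like cells at 0.339. Pfkp, a control point of glycolysis, was detected in 41.2% and the hexokinase gene Hk1 in 32.1% of choroid plexus cell-like cells. Slc2a1, the glucose transporter of the blood-brain barrier (chromosome 4, 119108711 to 119137983, plus strand), was found in 54.8% (49.1 to 60.4) of endothelial cell-like cells, 27.0-fold. Hk2 reached 24.8% (21.7 to 28.1) of microglia-like cells (72.9-fold) with 0 of 1688 excitatory neuron-like cells, Hif1a, the hypoxia-inducible factor, 35.4% of microglia-like cells (5.16-fold), and Vegfa, a growth factor of vessels, 29.95% of astrocyte-like cells (7.37-fold). Over all depths the choroid plexus fold of the glycolysis list was 1.02 (0.955 to 1.08).

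Nuclear-encoded genes of oxidative phosphorylation had their highest level, 0.645 (0.571 to 0.727), in choroid plexus cell-like cells, 1.26-fold (1.12 to 1.43) with 13 of 15 members higher (median log2 0.81, percentile 99.9), and their lowest, 0.268, in ependymal cell-like cells. The choroid plexus fold turned, in cells of all depths, to 0.770 (0.699 to 0.847). Ndufs1, a subunit of complex I, was most frequent in striatal projection neuron-like cells (15.9%) and Atp5a1, a subunit of ATP synthase, in choroid plexus cell-like cells (9.05%). Mitochondrial transcripts were highest in endothelial cell-like cells at 2.24 (2.08 to 2.41) per cell against 0.256, an 8.75-fold difference (8.07 to 9.47) with 13 of 13 members higher (median log2 2.94, percentile 100). Ependymal cell-like cells followed at 1.13 (4.07-fold), and microglia-like cells had 0.253, 0.879-fold (0.757 to 1.02), or 0.531-fold in cells of all depths. Per detected gene the microglia fold was instead 1.20 (1.07 to 1.34). The complex IV gene mt-Co1 was detected in 58.9% (53.3 to 64.4) of endothelial cell-like, 31.1% of ependymal cell-like and 1.91% of choroid plexus cell-like cells, and mt-Cytb in 32.2% of endothelial cell-like cells. Cytosolic ribosomal proteins showed the same leading class at 0.790 (0.695 to 0.895), 3.60-fold (3.16 to 4.09) with 16 of 16 members higher (median log2 1.88, percentile 99.99). Rpl13 was detected in 10.2% of endothelial cell-like and Rps14 in 7.14% of choroid plexus cell-like cells.

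Nuclear-retained long RNAs were highest in CA neuron-like cells at 5.22 (5.03 to 5.41) per cell, 1.44-fold (1.39 to 1.5) with 6 of 8 members higher (median log2 0.66, percentile 96.0), and lowest in microglia-like cells at 2.08. Per detected gene the CA fold turned to 0.930 (0.920 to 0.941). Malat1 was detected in 100% of the cells of each class. Meg3 ranged from 100% of excitatory neuron-like to 31.0% of choroid plexus cell-like cells, Rian reached 91.3% of inhibitory neuron-like and Miat 50.7% of CA neuron-like cells, and Neat1, the scaffold of paraspeckles, was found in 64.8% of oligodendrocyte-like and 0.580% of inhibitory neuron-like cells. Sex-linked genes, in a pool loaded from both sexes, were highest in choroid plexus cell-like cells at 1.5 (1.38 to 1.62), 1.30-fold (1.20 to 1.40) with 8 of 10 members higher (median log2 0.35, percentile 96.1), but 0.962-fold (0.900 to 1.03) in cells of all depths. Xist, the RNA that silences an X chromosome in females, was detected in 63.5% of microglia-like and 32.0% of CA neuron-like cells, and the Y-linked helicase gene Ddx3y in 6.37% of endothelial cell-like cells.

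The third comparison asked how microglia-like cells differ among themselves. Subclusters made without any list gene differed widely in the plaque-associated list, which is named after cells that gather at amyloid plaques. Subcluster 1 (381 cells, 20.97% of microglia-like cells) had 5.83 of these genes per cell and subcluster 0 (486 cells, 26.7%) had 1.07, a 5.47-fold difference (4.97 to 6.03) with 24 of 25 members higher (median log2 2.86, percentile 100). The homeostatic list ran the other way, at 4.04 in subcluster 1 and 6.27 in subcluster 0, 0.644-fold (0.606 to 0.685), with 17 of 18 members lower (median log2 -1.01, percentile 0). All depths were used here, and the median number of detected genes was 723 in subcluster 1 and 660 in subcluster 0.

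The subclusters fell apart by this list. Subcluster 3 (279 cells) had 4.78 plaque-associated genes per cell and subcluster 4 (274 cells) 4.03, whereas subcluster 2 (328 cells) had 1.48 and subcluster 5 (64 cells, led by neuronal genes) 1.30. Interferon-stimulated genes stood at 1.90 (1.74 to 2.07) in subcluster 3 and 1.70 (1.55 to 1.87) in subcluster 4, intervals that overlap, at 1.46 in subcluster 2 and 1.33 in subcluster 1, and at 0.934 in subcluster 0 and 0.875 in subcluster 5. Early response genes linked to tissue dissociation were also at their highest in subcluster 3, 0.401 (0.331 to 0.483) per cell, against 0.252 (0.196 to 0.319) in subcluster 4, 0.236 in subcluster 1, 0.167 in subcluster 0, 0.156 in subcluster 5 and 0.149 in subcluster 2. Median depth was 777 genes in subcluster 3 and 701 in subcluster 4. Subcluster 2 was led by Ms4a6b with the interferon-induced gene Oas2 and the apoptosis inhibitor gene Birc3, subcluster 3 by Nfkbiz and Baiap2l2, and subcluster 4 by Creb5 and Cd300lf.

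**Figure D3:**
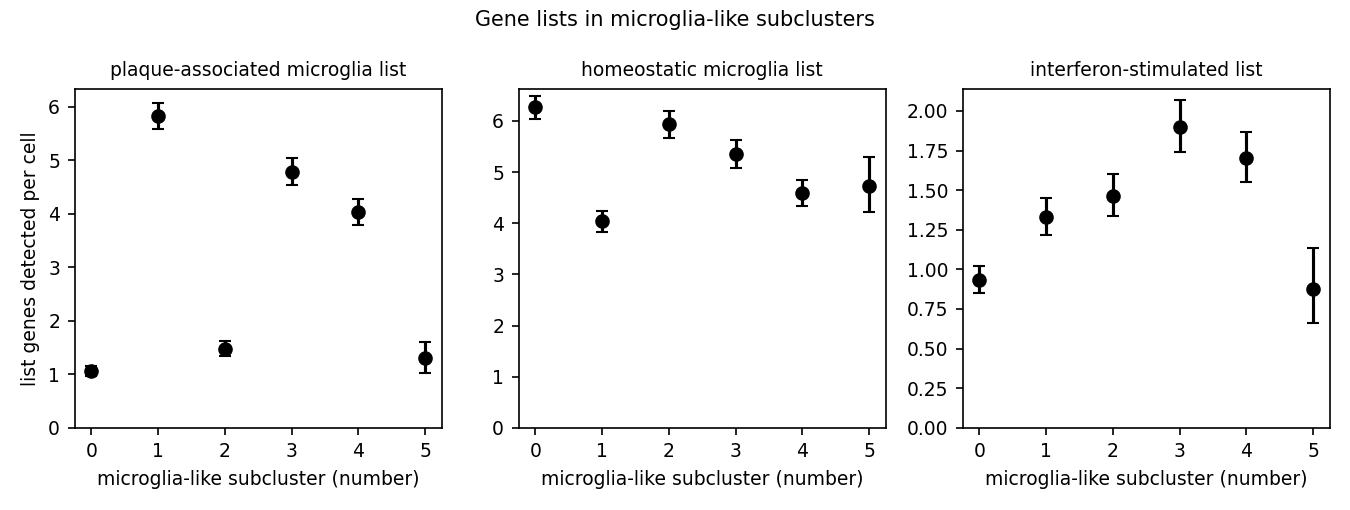
Points give list genes detected per cell (y axis) in the 6 microglia-like subclusters of at least 50 cells (x axis), with 95% Poisson intervals, for the plaque-associated, homeostatic and interferon-stimulated lists. Subclusters 1, 3 and 4 have 5.83, 4.78 and 4.03 plaque-associated genes per cell and the other subclusters at most 1.48.

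Subclusters 1 and 0 were chosen after the fact as the highest and lowest on the plaque-associated list, which raises their fold. The choice also favours this list's count of higher members and its percentile, since the random lists were scored on the same pair. With the pair chosen on 15 members and measured on the other 15, the same pair came out and the fold was 4.87 (4.30 to 5.53), or 6.37 (5.48 to 7.44) with the parts exchanged. In 10 simulated sets of microglia without subgroups the highest fold was 1.72 and the median 1.60. Those sets still split into 8 to 11 subclusters, so a split alone does not show that subgroups exist. They were drawn gene by gene and clustered on detection rather than on scores. Genes that vary together were not simulated. With a minimum of 1000 detected genes, where the subclusters were made and the pair chosen anew, the fold of the plaque-associated list was 3.08.

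Among plaque-associated genes, Apoe was detected in 43.6% of subcluster 1 and 3.09% of subcluster 0 cells, a 14.1-fold difference (8.32 to 25.8). Itgax was at 30.7% against 0.823% (37.3-fold, 14.2 to 139). Igf1, a growth factor (chromosome 10, 87858265 to 87937042, plus strand), was at 40.9% against 0.412% (99.5-fold, 27.1 to 829), and Dkk2, an antagonist of Wnt signals (chromosome 3, 132085292 to 132180304, plus strand), at 33.9% against 0.206% (165-fold, 29.0 to 6549). Gpnmb, a glycoprotein of lysosomes (chromosome 6, 49036546 to 49070929, plus strand), was found in 17.6% of subcluster 1 and 0 of 486 subcluster 0 cells, which allows up to 0.617%, so it was at least 28.5-fold higher. Lpl, a lipase (22.0% against 0.617%), Axl, a receptor for dying cells (32.3% against 2.88%), the growth factor gene Csf1 (29.9% against 1.85%), Clec7a (22.6% against 1.03%) and Myo1e (74.8% against 9.88%) followed. Trem2 differed less, at 19.7% against 11.1% (1.77-fold, 1.23 to 2.56), as did Timp2, an inhibitor of matrix proteases (18.4% against 8.44%). Neither Tyrobp, the adaptor of Trem2 (1.79-fold, 0.878 to 3.72), nor the ferritin gene Fth1 (0.729-fold, 0.327 to 1.55) was separated from equal shares. Lpl, Axl, Csf1, Clec7a, Myo1e and Apoe were named for this comparison after their values were seen.

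Of the homeostatic genes, Tmem119, a surface protein of microglia (chromosome 5, 113793729 to 113800516, minus strand), was at 2.89% in subcluster 1 and 18.3% in subcluster 0 (0.158-fold, 0.0760 to 0.296), Slc2a5 at 2.63% against 12.6% (0.209-fold), Crybb1 at 0.787% against 7.41% (0.106-fold, 0.0209 to 0.336) and Ecscr at 0.263% against 4.94% (0.0532-fold, 0.00129 to 0.326). P2ry12, the receptor that steers microglial processes to ADP (chromosome 3, 59216272 to 59262871, minus strand), fell outside the naming rule and was at 22.0% against 53.9% (0.409-fold, 0.316 to 0.525). Mef2c (1.08-fold), Fcrls (0.985-fold) and Gpr34 (0.903-fold) were close to equal. Tgfbr1 had a fold of 0.923 (0.797 to 1.07). Its shares of 85.0% (81.1 to 88.5) in subcluster 1 and 92.2% (89.4 to 94.4) in subcluster 0 nevertheless had intervals that do not overlap.

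The interferon list was 1.43-fold higher in subcluster 1 than in subcluster 0 (1.25 to 1.62) with 14 of 15 members higher (median log2 0.50, percentile 98.98). Ifi204 was at 10.5% against 3.70% (2.84-fold, 1.59 to 5.25) and Oas1a at 4.99% against 0.823% (6.06-fold, 2.01 to 24.5). Usp18, which limits interferon signalling (8.29-fold, 1.88 to 75.7), and the tetherin gene Bst2 (5.10-fold, 1.02 to 49.3) rest on few cells. With at least 1000 genes per cell Bst2 stood at 0.536-fold (0.00908 to 10.3), between subclusters made and chosen anew. Parp14 (1.17-fold), Ddx60 (1.05-fold), Rnf213 (1.04-fold) and the RNA sensor gene Ddx58 (0.757-fold) had the smallest folds. The MHC list was 1.72-fold higher (1.42 to 2.08), but with 6 of 9 members higher and a median log2 of 0.01 (percentile 33.2) this came from a few genes. Cd74 was at 8.92% against 0.617% (14.5-fold, 4.55 to 73.6) and Nlrc5 at 17.6% against 5.35% (3.29-fold, 2.06 to 5.39), while H2-D1 was equal (1.0-fold, 0.546 to 1.82). H2-Q7 (2.87-fold, 0.801 to 12.8), the class II activator gene Ciita (2.55-fold, 0.366 to 28.2), Psmb9, a subunit of the immunoproteasome (0.638-fold, 0.196 to 1.84), and the peptide transporter gene Tap1 (0.567-fold, 0.128 to 2.03) were not separated from equal shares. Subcluster 1 had 0.690 MHC genes per cell, against 0.9355 in subcluster 3 and 0.825 in subcluster 4. At a clustering resolution of 2 the folds were 2.44 for the interferon and 3.57 for the MHC list. With at least 1000 genes per cell the MHC fold was 1.25 (0.902 to 1.72), an interval that holds 1. Both alternatives made new subclusters and chose their own highest and lowest, so these folds are not for subclusters 1 and 0.

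Of the metabolic lists some separated the pair. Glycolysis and hypoxia genes were 2.05-fold higher in subcluster 1 (1.77 to 2.38) with 12 of 15 members higher (median log2 0.77, percentile 99.96), cholesterol genes 1.68-fold (1.48 to 1.90) with 11 of 13 (median log2 0.70, percentile 99.8), and lysosome genes 1.33-fold (1.24 to 1.43) with 16 of 20 (median log2 0.49, percentile 99.9). Per cell, subcluster 3 was not below subcluster 1 in these lists. Its levels were 1.37 for glycolysis, 1.54 for cholesterol and 4.975 for lysosome genes, against 1.28, 1.49 and 4.205 in subcluster 1. Per 1000 detected genes subcluster 1 was higher for glycolysis (1.67 against 1.55) and cholesterol (1.95 against 1.75). It was lower for lysosome genes (5.49 against 5.65). Nuclear-encoded oxidative phosphorylation genes did not separate subclusters 1 and 0 (1.01-fold, 0.786 to 1.29, with 3 of 6 higher). Mitochondrial transcripts were 0.709-fold (0.508 to 0.981) with 0 of 7 higher, but 1.01-fold (0.621 to 1.64) in cells of 600 to under 900 genes. Alzheimer disease risk genes were 0.885-fold (0.835 to 0.939) with 4 of 24 members higher, and complement genes 0.940-fold (0.848 to 1.04). Early response genes were at 1.42-fold (1.04 to 1.94) with 3 of 5 members higher. The interval held 1 in cells of 600 to under 900 genes (1.28, 0.815 to 2.0), per detected gene (1.33, 0.977 to 1.82) and with at least 1000 genes per cell (1.26, 0.627 to 2.56). The last of these folds is between subclusters chosen anew. The stress-induced transcription factor gene Atf3 was at 4.72% against 0.412% (11.5-fold, 2.75 to 102) and Nfkbiz at 7.87% against 3.91% (2.01-fold, 1.10 to 3.79), while Fos, Dusp1 and Hspa1b were each found in 0 of 381 subcluster 1 cells, which allows up to 0.787%, and in 0.412% of subcluster 0 cells. Markers of other cells were compared in the same pair. The perivascular macrophage markers were 0.173-fold (0.104 to 0.274), but only 1 of 9 could be tested singly, and Stab1 among them was itself detected in 18.4% of microglia-like cells. The synaptic list was 0.708-fold (0.642 to 0.781), the astrocyte markers 0.821-fold, and the oligodendrocyte markers 1.20-fold (0.936 to 1.54), and monocyte markers were too rare to test singly. Whether these subclusters hold different shares of 5xFAD and wild-type cells, or of female and male cells, was not analysed here.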

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

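All alternatives below except 4000 variable genes, Leiden resolutions of 0.5 and 2 and doublets kept were chosen after the data had been seen. Wherever the clustering changed, subcluster folds are for the highest and lowest of the new subclusters, not for subclusters 1 and 0. Of 102 values of the main class shares and list folds under alternatives, 59 stayed within the counting interval of the reported value. Another 43 moved beyond it and none reversed, and the cause was not tested. Class shares could not reverse under the rule used. Nor could the plaque-associated subcluster fold where the pair was chosen anew on that list. In cells of all depths the folds were 4.59 (plaque-associated), 4.84 (homeostatic), 7.18 (interferon) and 15 (MHC), and 1.65 for the oligodendrocyte and 2.16 for the reactive astrocyte list. Per detected gene they were 10.4, 10.9, 9.04, 18.9, 4.03 and 4.25 in that order. With at least 1000 detected genes per cell the folds were 9.45 (plaque-associated), 8.06 (interferon), 13.5 (MHC), 3.48 (oligodendrocyte list) and 3.82 (reactive astrocyte list). The shares were then 5.14% (astrocyte-like), 16.7% (excitatory neuron-like), 0.557% (microglia-like), 1.08% (oligodendrocyte-like) and 28.6% (unnamed), and the folds between microglia-like subclusters 3.08 (plaque-associated), 0.813 (homeostatic) and 1.25 (MHC, 0.902 to 1.72, which holds 1). At resolution 0.5 the subcluster folds were 4.03 (plaque-associated) and 0.751 (homeostatic) and the excitatory share 20.01%. At resolution 2 the subcluster folds were 7.34 (plaque-associated), 1.96 (early response), 0.708 (homeostatic), 2.44 (interferon) and 3.57 (MHC), the excitatory share 20.5% and the unnamed share 17.6%. With 4000 variable genes they were 0.719 (homeostatic), 1.75 (interferon) and 2.28 (MHC), with shares of 20.6% (excitatory) and 17.2% (unnamed). With doublets kept the shares were 10.5% (astrocyte-like), 20.3% (excitatory) and 17.8% (unnamed). In cells of 600 to under 900 genes 5 of 5 subcluster folds stayed within their intervals, but the early response interval then held 1. The class with the highest level was unchanged for 22 of 22 lists with 4000 variable genes and at resolutions 0.5 and 2, for 21 with doublets kept, for 20 with at least 1000 genes, for 18 per detected gene and for 14 in cells of all depths.

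Of 1033 values of other lists and single genes, 892 stayed within their intervals, 135 moved, and 6 whose reported interval lay on 1 side of 1 turned to the other side; the cause was not tested. In cells of all depths these were the early response list in microglia-like cells (0.630), and oxidative phosphorylation (0.770) and sex-linked genes (0.962) in choroid plexus cell-like cells. Per detected gene they were the synaptic list (0.971) and nuclear long RNAs (0.930) in CA neuron-like cells, and with at least 1000 genes per cell Bst2 between microglia-like subclusters (0.536, 0.00908 to 10.3). Counting also values whose reported interval held 1, those on the other side of 1 numbered 6 with 4000 variable genes, 6 at resolution 0.5, 8 at resolution 2, 4 with doublets kept, 10 with at least 1000 genes, 3 in cells of all depths and 3 per detected gene. Comparisons by genotype and by sex, and their alternatives, were not run because cells could not be assigned here to animals. Thinning to 500 UMIs and CPM need counts and were not run, and the minimum of 500 UMIs removes no cell. The filter on mitochondrial share also needs counts. As a share of the score it removes no cell, since the highest was 0.831%. Unless stated otherwise, intervals cover counting error in 1 pool, so differences between animals limit every value to an unknown degree.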

Other observations

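The tests on tissue dissociation and on nuclei against whole cells were chosen only after the result was seen, as were the tests on frequent members used to weigh astrocyte RNA and dissociation, the subclusters of astrocyte-like and oligodendrocyte-like cells and the genes named in them. Levels and shares within these subclusters are for cells of all depths. Astrocyte-like cells split into 13 subclusters, and 1 of them, subcluster 4 (495 cells, median 937 detected genes), joined reactive and interferon genes. It had 3.16 (3.0 to 3.32) reactive astrocyte genes per cell, against 0.524 (0.485 to 0.566) in subcluster 2 (1248 cells, median 991 genes), a pair again chosen as highest and lowest. Gfap was detected in 64.7% of subcluster 4 and 7.69% of subcluster 2 cells. Subcluster 4 also had 69.3% for C4b, 33.3% for Ggta1, an enzyme of cell-surface sugars, 30.9% for Osmr, 36.6% for Stat3, a transcription factor of the reactive response, and 16.2% for the hyaluronan receptor gene Cd44. Its interferon-stimulated level of 1.75 (1.63 to 1.87) per cell was above the next highest of 0.843 in subcluster 11, with Ddx60 in 26.1%, Trim30a in 16.2% and Oasl2 in 11.5% of its cells, and Sulf1, Bcl3, S1pr3 and the interferon-induced gene Gbp5 led it. Subcluster 3 (506 cells, led by Myoc) had Gfap in 48.8% and C4b in 41.3% but a reactive level of 1.72, and subcluster 2, led by Unc13c, had the highest cholesterol level at 2.32 per cell, though per 1000 detected genes subcluster 3 was higher (2.58 against 2.33).

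Oligodendrocyte-like cells differed in which disease-associated genes they carried. In subcluster 0 (790 cells, median 753 detected genes) Anln was detected in 64.3%, Il33 in 15.6% and C4b in 20.1% of cells, whereas in subcluster 4 (637 cells, median 669 genes) Anln was in 18.7%, Il33 in 46.5% and C4b in 36.7%. The whole list was highest in subcluster 5 (448 cells, median 704 genes) at 1.92 (1.80 to 2.06) per cell and lowest in subcluster 7 (183 cells, median 795 genes) at 0.940.

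Microglia-like subcluster 1 had 5.47 times as many plaque-associated genes per cell as subcluster 0, and depth as the whole cause is argued against by a fold of 5.67 (4.93 to 6.54) in cells of 600 to under 900 detected genes. RNA of astrocytes is argued against by astrocyte markers at 0.821-fold (0.664 to 1.01) and by the 5 of 12 that were frequent enough to test, each above the 3-cell limit in both subclusters and together 0.824-fold (0.665 to 1.02), such as Slc1a2, found in 98.9% of astrocyte-like cells but in 6.56% of subcluster 1 against 9.47% of subcluster 0. The fold of the early response list over that of the plaque-associated list was 0.259 (0.172 to 0.390), yet tissue dissociation stays open, since over the 5 of 20 genes that could be tested it was 0.323 (0.198 to 0.529) and 3 of these were higher, among them Atf3 (11.5-fold, 2.75 to 102). A rule tried before this, the share of the median list member against the limit of 0.617% set by 3 cells, gave the opposite reading of both, with RNA of astrocytes open (0.525%) and dissociation argued against (0.805%). The genotype of the animals stays open and was not tested, because cells could not be assigned to animals.

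An unnamed cluster of 272 cells carried genes of both microglia and oligodendrocytes, with a median of 999 detected genes against 708 in microglia-like and 678 in oligodendrocyte-like cells, a median doublet score of 0.0672 against 0.0040 and 0.0052, and 483 such cells when doublets were kept. That score was not particular to this cluster. The Th-led inhibitory neuron-like cluster of 149 cells also had a median of 0.0672, and the cluster led by Cdhr1 and Eomes 0.0685. The mixed cluster held 16 microglia markers at 87.8% and 11 oligodendrocyte markers at 91.8% of their level in their own class, and 25 long non-coding RNAs of oligodendrocytes at 88.8%. The ratio of the last 2 values was 0.968 (0.876 to 1.10), as 2 nuclei or cells under 1 barcode would give. Its range comes from redrawing the long RNAs and the markers at random with repeats, so it reflects spread among genes. Adhering or engulfed myelin RNA would leave the long non-coding RNAs behind only if they stay in the nucleus. They were picked by annotation and by their frequency in oligodendrocyte-like cells, and their place in the cell was not checked. The ratio therefore does not decide between these 2 explanations. Chance pairing over the whole pool is argued against, since barcodes with microglia genes were 8.86 times (7.28 to 10.8) as frequent per oligodendrocyte barcode as per astrocyte or neuron barcode, at 41.9 per 1000 (36.5 to 47.8) against 10.5 (8.21 to 13.1) for astrocytes and 3.67 for neurons, and 18.4 (12.9 to 25.5) for oligodendrocyte precursors. Pairing among the cells of 1 preparation stays open, and no biological explanation was tested.

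Some wells were loaded with isolated microglia, but no barcode was tied here to that preparation. Microglia-like cells had 0.253 mitochondrial genes per cell (746 cells) against 0.161 in the neuron classes (6958 cells). The ratio of 1.58 (1.34 to 1.84) lies between the values set for nuclei and for whole cells, so these cannot be told apart. Per detected gene over all depths, microglia-like cells had 1.20 times (1.07 to 1.34) the mitochondrial level of other cells. A filter on mitochondrial share before the matrix was made may also have removed whole cells, but the highest share of any cell, 0.831% of its score, decides nothing without the unfiltered cells. No biological explanation was tested.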
